A study of Mus musculus with 6 samples.

How the data were processed

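RNA of 6 samples was measured on Affymetrix MOE430_2 arrays, 3 of Ebf2-positive and 3 of Ebf2-negative cells from mouse bone marrow, both gated as negative for CD45, TER119 and CD31. Per the labels' protocols, cells were used fresh and untreated, RNA was extracted with the RNeasy Micro kit, and the biotin-labelled material was amplified and hybridized by the array maker's protocol. Per the series design text, 1000 or 2000 cells gave each RNA sample and amplification ran in a dual round. Which array had which cell number, how Ebf2 was detected in the sort and how many animals were used are not given in the sources used here.

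The values deposited by the authors are 1 intensity per probe set and array, made with RMA, which corrects background, normalizes quantiles between arrays and summarises the probes of a set, per the submitters' processing notes. The version of the RMA software is not given in the sources used here. RMA usually gives log2 values, but the deposited intensity values are on a linear scale, as their range shows, and log2 was taken before any test. The planned test allowed for this. Quantile normalization forces the arrays to nearly the same distribution, so a difference in the total RNA per cell between groups cannot be seen, and a large block of genes that rises in a group lowers the others. Amplification of RNA from few cells adds spread to dim genes and favours the 3' ends of transcripts. Hybridization signal also compresses differences at both ends of the range, so folds of genes dim in a group are not exact.

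The table has 45101 probe sets, of which 64 are control probe sets and were left out of the tests. Genes were named from GEO's annotation of the array, which pairs 34945 probe sets with exactly 1 gene, 932 with several and 9160 with none. The Entrez identifiers of 34741 probe sets were found in a RefSeq gene table for the assembly GRCm38.p6, which changed 0 symbols, and no coordinates were used. Each of 18193 genes was represented by the probe set with the highest mean over the 6 arrays among those naming only that gene, which meant a choice for 9010 genes. All 45037 non-control probe sets were also tested singly, and 6822 were called, 2879 higher and 3943 lower. That count fell to 4076 without Ebf2-negative replicate 1 and 3526 without Ebf2-negative replicate 3.

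Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 32 gene lists hold 677 distinct genes, of which 622 were measured. They were written from textbook knowledge and, like the groups, the test, the naming rule and most alternatives, were fixed before the data were examined. Lists were tested with camera, which asks whether a list's genes differ more than other genes do, with a preset inter-gene correlation of 0.01. With the correlation estimated from the arrays, 0 of the 32 lists passed, against 23 with the preset value (17 higher, 6 lower). The test fry was run as well. Its directional p asks whether a list's genes move, on balance, in the same direction, its mixed p whether they change in either direction, and neither compares a list with other genes. Counts of called members are given over all genes and adjusted over the list alone.

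Genes named in the text were Ebf2 and the genes of the sort markers, the 15 with the largest positive and the 15 with the largest negative difference among called genes with non-overlapping groups (clone and model identifiers left out), and up to 4 called members of each list with the largest differences, or up to 2 bright members where none passed. Some further genes were named after their values were seen, as stated beside them. A planned marker gene for TER119 was not analysed here.

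The alternatives were a further quantile normalization, centring on the median or the 75th percentile, filters on dim probe sets, the mean of a gene's probe sets, leaving out probe sets that can cross-hybridise, other variance models, array weights, a minimum log2 difference of 1 (treat), the replicate number as a block, other list tests, and leaving out each array in turn. Centring on the poly-A controls and leaving out both arrays numbered 2 were added after seeing the data. The number of arrays, 3 per group, limits the precision. The gene test was checked on simulated data with 18193 genes and this design. It called 5.88% of 68 genes changed by 1 on the log2 scale, 60.6% of 66 changed by 2 and 97.0% of 66 changed by 4. There were 7 false calls (6.09% of all calls). Far fewer genes were changed in the simulation than were called in the data, which makes its adjusted threshold stricter. These rates therefore cannot be carried over to the data. Comparisons of 3 against 3 single values used exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.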

Results

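The series holds 6 microarray profiles of cells sorted fresh from the bone marrow of untreated wild-type C57BL/6 mice. Both groups were gated as negative for CD45, the surface protein of leukocytes, TER119, a surface marker of erythroid cells, and CD31, a surface protein of endothelial cells, which leaves the non-haematopoietic, non-endothelial stroma as the target of the gate. Within that gate, 3 arrays measured cells positive for Ebf2, an early B-cell factor family transcription factor found in immature mesenchymal cells, and 3 measured cells negative for it. RNA came from 1000 or 2000 cells per sample, amplified before hybridization to the Affymetrix MOE430_2 array. The labels imply 1 comparison, Ebf2-positive against Ebf2-negative cells, which asks which genes set the Ebf2-expressing part of the marrow stroma apart from the rest of the gate. That rest did not look like stroma alone: the mean log2 signal of erythroid genes was 9.38 in Ebf2-negative and 5.68 in Ebf2-positive cells. The differences below therefore cannot be read as differences between kinds of stroma. A difference in the mix of cells was not separated from them. All differences below are Ebf2-positive minus Ebf2-negative on the log2 scale of the RMA signal, with n = 3 arrays in each group. The labels do not say whether replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

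The 3 Ebf2-negative arrays resembled each other more closely than the 3 Ebf2-positive arrays did. Pearson correlations across the 45037 non-control probe sets ran from 0.968 to 0.977 within the Ebf2-negative group, from 0.919 to 0.924 within the Ebf2-positive group and from 0.825 to 0.873 between groups, where probe sets are not independent replicates. The first principal component, with 64.3% of the variance, separated the groups. The next component, with 13.6%, set Ebf2-positive replicate 2 (-113) apart from Ebf2-positive replicates 1 and 3 (57.2 and 55.7). Median intensity lay between 13.0 and 14.0 on every array. The ratio of 3' to 5' actin probe sets, a measure of 3' bias after amplification, was 31.4, 14.0 and 27.3 on the Ebf2-positive arrays and 24.2, 15.9 and 19.5 on the Ebf2-negative arrays (two-sided exact permutation p = 0.7). The smallest p that 3 against 3 arrays allow in such a test is 0.1.

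Ebf2 itself followed the sort. Its signal was 8.33 ± 0.41 (SD, n = 3) in Ebf2-positive and 3.66 ± 0.49 in Ebf2-negative cells, a log2 difference of 4.67 (SE 0.33), or 25.5-fold (limma with Benjamini-Hochberg adjustment, adjusted p = 0.000476). All 3 of its probe sets were called higher, the other two by 3.90 and 1.36. Ptprc, which encodes CD45, was at 5.68 ± 1.81 in Ebf2-positive and 8.33 ± 0.41 in Ebf2-negative cells. That difference of -2.65 did not pass the threshold (adjusted p = 0.0698), since Ebf2-positive replicate 3 stood at 3.59 and replicates 1 and 2 at 6.68 and 6.76. Without Ebf2-positive replicate 3 the difference was -1.61 and passed (adjusted p = 0.0162). A second Ptprc probe set differed by -0.14 (adjusted p = 0.728 among probe sets). It was near the lower end of the signal range in both groups, at 2.43 ± 0.09 and 2.57 ± 0.37, and so says little about Ptprc. Pecam1, which encodes CD31, was near the lower end of the signal range in both groups, at 3.57 ± 0.52 and 3.01 ± 0.70 (difference 0.56, adjusted p = 0.403).

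**Figure D1:**
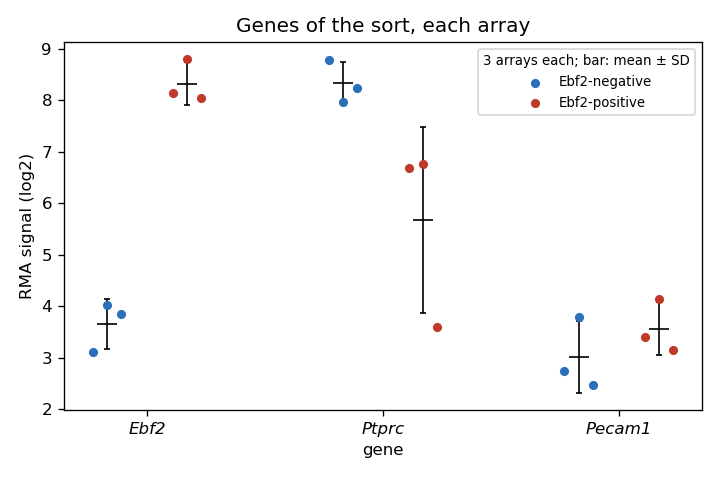
RMA signal (log2, vertical axis) of Ebf2, Ptprc and Pecam1 on each array (points; red, Ebf2-positive; blue, Ebf2-negative), with bars for the mean and SD of 3 arrays. The Ebf2 groups lie apart at 8.33 and 3.66, 1 Ebf2-positive array has Ptprc at 3.59, and the Pecam1 values of the groups overlap.

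Extracellular matrix, fibroblast and mural-cell genes were higher in the Ebf2-positive cells, and erythroid and cell-division genes were higher in the Ebf2-negative cells, although none of these lists passed with an estimated correlation between genes (adjusted p = 0.209, 0.109, 0.156, 0.116 and 0.156). Of 18193 genes tested, 4430 (24.4%) passed an adjusted p of 0.05, 1961 of them higher and 2469 lower in Ebf2-positive cells. At least 4-fold differences were found for 1095 genes called higher and 1080 called lower, and at least 32-fold differences for 92 and 35. All 4430 called genes had groups that did not overlap, among 7814 genes (43.0%) with this property, where chance gives 10%. The median difference over all genes was 0.07, and centring each array on its 75th percentile shifted it by 0.12. Among called genes, 44.3% were higher. After centring on the poly-A controls added to the samples, which were brighter on the Ebf2-positive arrays (12.31 ± 0.21 against 9.82 ± 0.99), only 1.43% of called genes were higher, a scaling referred to below as poly-A centring. It shifted every difference by the same -2.49, so each difference here is relative to the other genes on the array and not to an absolute amount of RNA per spike-in. Leaving out Ebf2-negative replicate 3 lowered the count to 2690 genes, 1294 higher and 1396 lower, and leaving out Ebf2-negative replicate 1 lowered the count of lower genes to 1586.

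The genes with the largest positive differences included genes of matrix proteins and of pericytes. Ccn3, a matricellular protein of the CCN family, stood at 11.55 ± 0.10 in Ebf2-positive and 3.22 ± 0.61 in Ebf2-negative cells, a difference of 8.33 (SE 0.33), or 321-fold (adjusted p = 0.00014). It was followed by Aspn, the small leucine-rich proteoglycan asporin (7.64, SE 0.24, 199-fold), Tnxb, the matrix glycoprotein tenascin-X (7.62), Dpt, the collagen-binding protein dermatopontin (7.53), Col14a1, a fibril-associated collagen chain (7.45), and Efemp1, a fibulin of elastic tissue (7.39). Acta2, smooth muscle alpha-actin, rose from 5.44 ± 0.60 to 12.44 ± 0.10 (7.01). Rgs5, a G-protein signalling regulator of pericytes, differed by 6.60, and Kcnj8, a potassium channel subunit of mural cells, by 6.56. The remaining genes of the first 15 were Efhd1, a calcium-binding protein of mitochondria (7.07), Igfbp6, a binding protein of insulin-like growth factors (6.95), Meg3, an imprinted long noncoding RNA (6.84), Fndc1, a fibronectin-domain protein (6.80), Ahnak2, a scaffold protein (6.72), and Aoc3, an amine oxidase of smooth muscle and fat cells (6.72).

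The genes with the largest negative differences include genes of red cells, of cell division and of basophils. Rhag, a membrane glycoprotein of the erythroid Rh complex, was at 2.07 ± 0.35 in Ebf2-positive and 9.50 ± 0.21 in Ebf2-negative cells, a difference of -7.43 (SE 0.25), or 173-fold (adjusted p = 0.000116). Slc4a1, the anion exchanger of the red cell membrane, Trim10, an erythroid RING-finger protein (-5.73), Tal1, a transcription factor of haematopoiesis (-5.61), and Bcl11a, a regulator of globin switching (-5.56), were also among the 15, as was Cldn13, a claudin (-5.62). Those of cell division were Trip13, an ATPase of the mitotic checkpoint (-7.27, 154-fold), Cdc7, a kinase that starts DNA replication (-5.61), Ect2, an exchange factor of cytokinesis (-5.44), and Cdca5, a regulator of sister chromatid cohesion (-5.52). Cdca5 lost its call without Ebf2-negative replicate 1 (adjusted p = 0.0552) or replicate 3 (adjusted p = 0.0513). Mcpt8, a basophil protease, differed by -5.89. Tspan8, a tetraspanin (-6.35), Tlcd4 (-6.31), Hmgb3, a chromatin protein of blood progenitors (-5.78), and Tmcc2 (-5.66) completed the group.

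**Figure D2:**
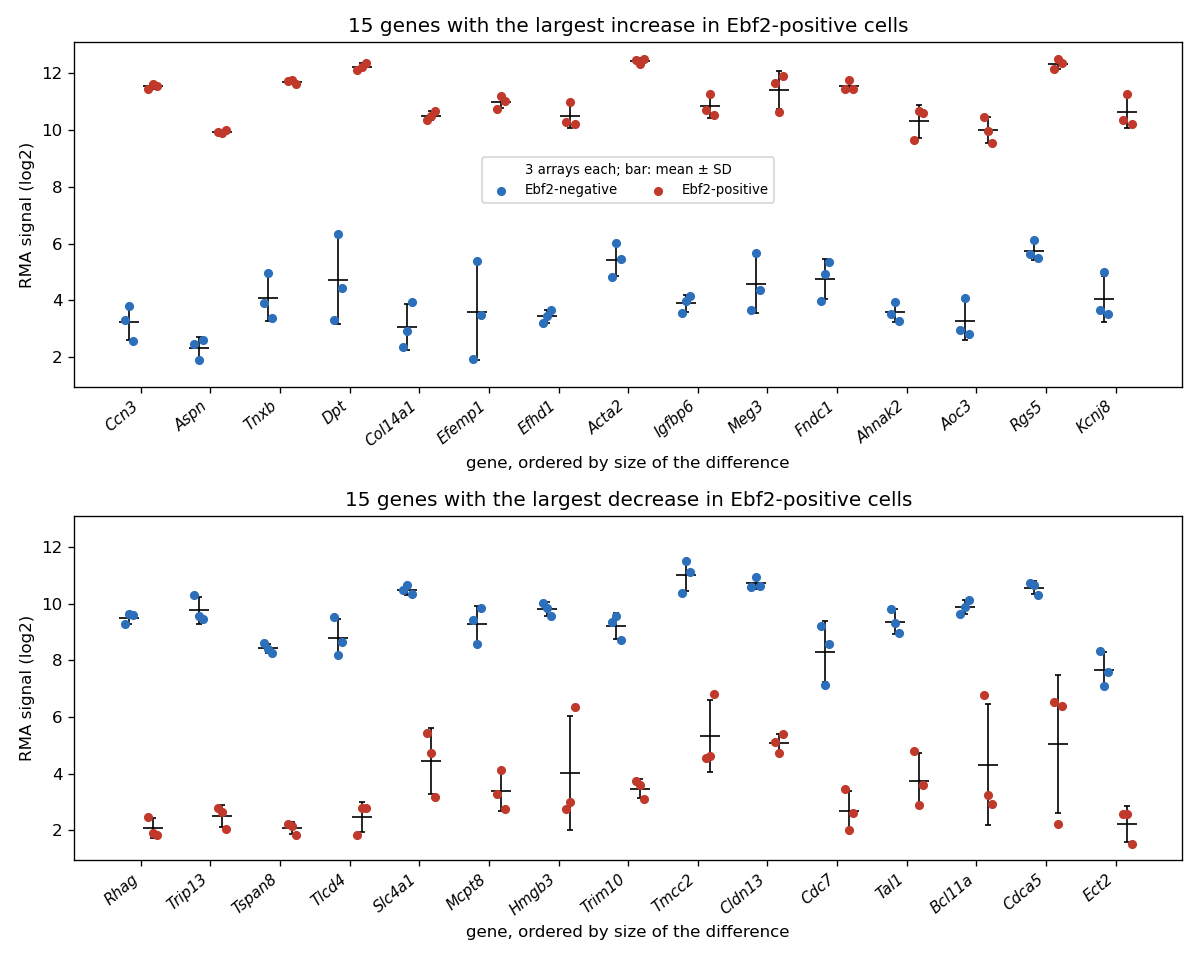
RMA signal (log2, vertical axes) on each array (points; red, Ebf2-positive; blue, Ebf2-negative) of the 15 genes with the largest positive difference (upper panel) and the 15 with the largest negative difference (lower panel), with bars for the mean and SD of 3 arrays. The groups do not overlap for any of these genes, from Ccn3 (8.33) to Kcnj8 (6.56) and from Rhag (-7.43) to Ect2 (-5.44).

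Fibroblast, pericyte and matrix genes rose as groups, among the 32 gene lists tested. Of 23 measured fibroblast and periosteal genes, 22 were higher and 0 lower, the same counts when adjusted over the list alone, with a median difference of 4.90 (camera adjusted p = 3.18e-19; adjusted p = 0.109 with an estimated correlation). Aspn, Dpt and Col14a1 led this list with Mfap5, a microfibril protein (6.51). Of 20 pericyte and smooth muscle genes, 17 were higher and 0 lower (19 and 0 adjusted over the list alone), with a median of 4.10 (camera adjusted p = 1.85e-13; adjusted p = 0.156 with an estimated correlation). Beside Acta2, Rgs5 and Kcnj8 they included Tpm2, a tropomyosin of contractile cells (5.20). Of 28 fibrillar and basement membrane matrix genes, 26 were higher and 0 lower, also when adjusted over the list alone, with a median of 3.85 (camera adjusted p = 1.27e-16; adjusted p = 0.209 with an estimated correlation). Col3a1, a fibrillar collagen chain, reached 13.63 ± 0.12 against 8.24 ± 0.52 (5.39), Mmp2, a gelatinase, differed by 5.27, Nid1, a basement membrane linker, by 4.98 and Timp3, a metalloproteinase inhibitor, by 4.85. With poly-A centring the medians of the fibroblast, pericyte and matrix lists were 2.41, 1.60 and 1.36. Then 16, 11 and 10 of their genes were called higher and 1, 2 and 1 lower.

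Of 27 measured stromal progenitor genes, 14 were higher, 1 lower and 12 not called, the same counts adjusted over the list alone, with a median of 1.25 that became -1.25 with poly-A centring (camera adjusted p = 9.05e-06; adjusted p = 0.347 with an estimated correlation). The higher members include Ebf2, the gene of the sort. Thy1, a surface glycoprotein of fibroblasts, differed by 5.41, Prrx2, a paired-type homeobox factor of mesenchyme, by 4.17 and Ebf1, the paralogue of Ebf2 needed for B-cell development, by 4.11 (10.28 ± 0.66 against 6.17 ± 0.64). Several genes were looked up after their values were seen. Pdgfra and Pdgfrb, receptors of platelet-derived growth factor, were higher by 3.38 and 2.85. Cxcl12, the chemokine that retains blood progenitors in the marrow, was bright in both groups at 11.97 ± 0.56 and 11.53 ± 0.83 (0.44, adjusted p = 0.557), and Lepr, the leptin receptor of perivascular stroma (-0.65, adjusted p = 0.421), and Ebf3 (0.20, adjusted p = 0.766) did not pass. The lower member was Grem1, an antagonist of bone morphogenetic proteins (-1.11), which lost its call without any of the Ebf2-positive arrays or Ebf2-negative replicates 2 and 3 (adjusted p up to 0.109, without Ebf2-negative replicate 3).

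Lists of haematopoietic support and of the fat, bone and cartilage lineages had smaller median differences than the fibroblast, pericyte and matrix lists. Each of these list calls was lost on leaving out at least 1 of the arrays. Of 20 niche factor genes, 6 were higher and 0 lower, also adjusted over the list alone, with a median of 0.79, or -1.71 with poly-A centring (camera adjusted p = 0.0196, but 0.103 without Ebf2-positive replicate 2 and 0.054 without Ebf2-negative replicate 3; adjusted p = 0.538 with an estimated correlation). Tgfb2, a transforming growth factor (4.54), Jag1, a Notch ligand (3.71), Igf1, an insulin-like growth factor (3.50), and Igfbp5, which binds it (2.56), were the largest. Of 21 adipocyte and lipid genes, 7 were higher and 0 lower (9 and 1 adjusted over the list alone), with a median of 0.57, or -1.92 with poly-A centring (camera adjusted p = 0.0321, but 0.108 without Ebf2-positive replicate 2; adjusted p = 0.538 with an estimated correlation). Scd1, a fatty acid desaturase (2.50), and Zfp423, a preadipocyte regulator (2.30), were among them, while 3 members were higher without Ebf2-negative replicate 1 or replicate 3 and 2 lower without Ebf2-positive replicate 2. Of 19 osteoblast genes, 7 were higher and 1 lower, also adjusted over the list alone, with a median of 0.33, or -2.16 with poly-A centring (camera adjusted p = 0.0457; adjusted p = 0.347 with an estimated correlation). This call held only without Ebf2-negative replicate 2, and adjusted p was 0.0542, 0.0939 and 0.0804 without Ebf2-positive replicates 1, 2 and 3 and 0.0575 and 0.0769 without Ebf2-negative replicates 1 and 3, where 3 and 4 members were higher, and 2 members were lower without Ebf2-positive replicate 2. Col1a1 and Col1a2, the chains of type I collagen, differed by 3.18 and 2.85, and Smpd3, a sphingomyelinase of skeletal tissue, by 2.81. Col1a1, Col1a2 and Sparc, also called higher, belong to the matrix list too, so the osteoblast result in part recounts that list. Dmp1, a matrix protein of osteocytes named after its value was seen, was lower (-2.79) but not without Ebf2-negative replicate 1 (adjusted p = 0.102) or replicate 2 (adjusted p = 0.092).

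Of 20 chondrocyte genes, 3 were higher and 0 lower, also adjusted over the list alone, with a median of 1.20, or -1.29 with poly-A centring (camera adjusted p = 0.0261; adjusted p = 0.676 with an estimated correlation). The 3 were Prg4, the joint lubricant lubricin (6.09, 68.1-fold), Comp, a cartilage and tendon matrix protein (3.78), and Chad, a leucine-rich cartilage protein (3.06). The list mean was 7.26 and 7.58 on Ebf2-positive replicates 1 and 3 and 4.55 on Ebf2-positive replicate 2, against 4.68, 5.51 and 4.87 on the Ebf2-negative arrays. Without Ebf2-positive replicate 2, 14 members were higher (camera adjusted p = 2.07e-07), and the call was lost without Ebf2-positive replicate 1 (0.117), Ebf2-positive replicate 3 (0.178) or Ebf2-negative replicate 1 (0.0575).

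**Figure D3:**
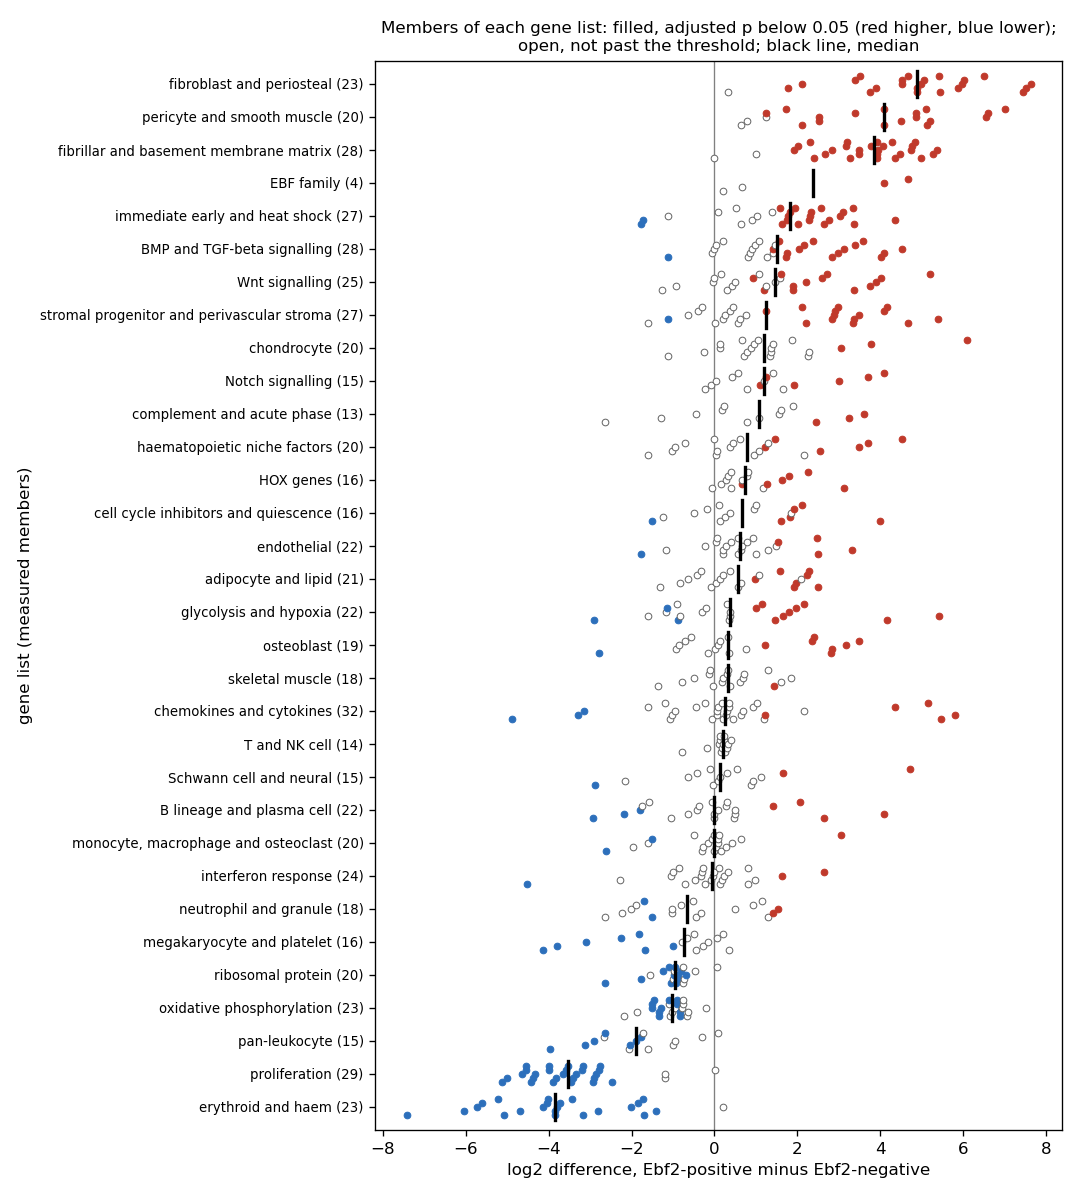
Log2 difference, Ebf2-positive minus Ebf2-negative (horizontal axis), of each measured member of the 32 gene lists (points; filled red or blue, called higher or lower; open, not called), with a black line at the median. Medians run from 4.90 for fibroblast genes to -3.85 for erythroid genes, and poly-A centring shifts all of them by the same -2.49.

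Ligands, receptors and inhibitors of developmental signalling pathways were higher in Ebf2-positive cells. Of 28 BMP and TGF-beta genes, 15 were higher and 1 (Grem1, lost without single arrays as given above) lower, or 17 and 1 adjusted over the list alone, with a median of 1.51, or -0.98 with poly-A centring (camera adjusted p = 2.59e-06; adjusted p = 0.347 with an estimated correlation), and 9 were higher without Ebf2-negative replicate 3. Beside Tgfb2, the ligands Bmp2 (4.10) and Tgfb3 (4.03) and the receptor Tgfbr2 (3.60) had the largest differences. Of 25 Wnt genes, 13 were higher and 0 lower (17 and 1 adjusted over the list alone), with a median of 1.47, or -1.02 with poly-A centring (camera adjusted p = 4.42e-06; adjusted p = 0.179 with an estimated correlation), and 8 were higher without Ebf2-negative replicate 3. They included the secreted Wnt inhibitor Dkk2 (5.20), the noncanonical ligand Wnt5a (4.01) and its receptor Ror2 (3.76). Of 15 Notch genes, 6 were higher and 0 lower (7 and 0 adjusted over the list alone), with a median of 1.20, or -1.29 with poly-A centring (camera adjusted p = 0.000547; adjusted p = 0.303 with an estimated correlation), and 4 were higher without Ebf2-negative replicate 1. The receptors Notch3, the form of mural cells (4.10), and Notch1 (1.91) rose with the target gene Heyl (3.01). Of the 4 EBF genes, Ebf1 and Ebf2 were higher and 0 were lower, also adjusted over the list alone, with a median of 2.39, or -0.11 with poly-A centring (camera adjusted p = 0.0196, but 0.0551 without Ebf2-positive replicate 2; adjusted p = 0.337 with an estimated correlation). Since the cells were sorted on Ebf2, its rise was set by the gate, and the list was not tested without it. Ebf1 was the only other member called. Of 16 HOX genes, which mark position along the body axis, 6 were higher and 0 lower, also adjusted over the list alone, with a median of 0.73, or -1.76 with poly-A centring (camera adjusted p = 0.00312; adjusted p = 0.156 with an estimated correlation). Hoxa10 differed by 1.80, and the count fell to 2, 3, 1, 2 and 2 without Ebf2-positive replicates 2 and 3 and Ebf2-negative replicates 1, 2 and 3.

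Genes of erythroid, megakaryocytic and general leukocyte identity were lower in Ebf2-positive cells. Of 23 erythroid and haem genes, 0 were higher and 22 lower, also adjusted over the list alone, with a median of -3.85 (camera adjusted p = 7.82e-16; adjusted p = 0.116 with an estimated correlation). Tfrc, the transferrin receptor, and Car1 and Car2, carbonic anhydrases of red cells, all looked up after their values were seen, fell by 4.03, 4.04 and 3.73. The exception, Hba-a1, an alpha-globin gene, had a signal near the bottom of the range in both groups (0.20, adjusted p = 0.703). Of 16 megakaryocyte and platelet genes, 0 were higher and 7 lower, also adjusted over the list alone, with a median of -0.72 (camera adjusted p = 0.000629; adjusted p = 0.209 with an estimated correlation). Nfe2 (-4.14) and Gata1 (-3.80) are transcription factors shared with the erythroid lineage, while Pf4 (-3.10) and Ppbp (-2.24) encode platelet chemokines. Of 15 pan-leukocyte genes, 0 were higher and 7 lower (0 and 9 adjusted over the list alone), with a median of -1.90 (camera adjusted p = 1.86e-05; adjusted p = 0.209 with an estimated correlation). Ikzf1, the lymphoid and progenitor transcription factor Ikaros, was at 6.20 ± 0.72 against 10.17 ± 0.09 (-3.96), Vav1, a haematopoietic exchange factor, differed by -3.12 and Was, an actin regulator of blood cells, by -2.90. The count of lower pan-leukocyte genes was 11 without Ebf2-positive replicate 2 and 4 without Ebf2-negative replicate 3.

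The lists of B-lineage, T and NK cell, and monocyte, macrophage and osteoclast genes did not pass as groups. Of 22 B-lineage and plasma cell genes, 4 were higher and 3 lower (4 and 4 adjusted over the list alone), with a median of 0.00 (camera adjusted p = 0.944). Higher members were Ebf1, Prdm1, a transcriptional repressor that promotes plasma cell fate and is also used outside the lineage (2.64), and, named after their values were seen, Xbp1, a secretory pathway factor (1.41), and Sdc1, a syndecan (2.06; lost without Ebf2-positive replicate 3 or Ebf2-negative replicates 1 and 3, adjusted p up to 0.0765). Lower members were Cd24a, a surface protein of immature blood cells (-2.93), Ighm, the immunoglobulin mu chain (-2.17), and, named likewise, Pou2af1, a B-cell coactivator (-1.80), which was lost on leaving out any array but Ebf2-negative replicate 2 (adjusted p up to 0.0974, without Ebf2-negative replicate 3). None of 14 T and NK cell genes was called, over all genes or adjusted over the list alone (median 0.20, camera adjusted p = 0.371). The brightest were Zap70, a T-cell receptor kinase (0.16, adjusted p = 0.697), and Nkg7, a cytotoxic granule protein (-0.79, adjusted p = 0.224). Of 20 monocyte, macrophage and osteoclast genes, 1 was higher and 2 lower (1 and 1 adjusted over the list alone), with a median of -0.01 (camera adjusted p = 0.755). Ctsk, a collagen-degrading protease of osteoclasts and fibroblasts, was higher (3.06), and Mrc1, the macrophage mannose receptor (-2.62), and Mmp9, a gelatinase (-1.51), were lower. Mmp9 lost its call without Ebf2-positive replicates 1 and 2 or Ebf2-negative replicates 2 and 3 (adjusted p up to 0.123, without Ebf2-negative replicate 3).

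Of 18 neutrophil and granule genes, 2 were higher and 2 lower, also adjusted over the list alone, with a median of -0.66 (camera adjusted p = 0.293). Mpo (1.42, 11.26 ± 0.11 against 9.85 ± 0.53) and Prtn3 (1.53, 9.12 ± 0.31 against 7.59 ± 0.64), enzymes of primary granules, were higher in Ebf2-positive cells. Both lay well above the lower end of the signal range in each group. Chil3, a chitinase-like protein of neutrophils (-1.69), and Mmp9 were lower. These calls were lost with fewer arrays: that of Mpo without Ebf2-negative replicate 3 (1.39, adjusted p = 0.0643), that of Prtn3 without Ebf2-positive replicates 1 and 2 and Ebf2-negative replicates 1 and 3 (differences of 1.18 to 1.59, adjusted p up to 0.0753) and that of Chil3 without Ebf2-positive replicate 1 or any Ebf2-negative array (-1.73 to -1.48, up to 0.0666), the highest p always without Ebf2-negative replicate 3, with Mmp9 as above. Without Ebf2-positive replicate 2, 8 members were lower and 1 higher and the list was called lower (camera adjusted p = 0.0112). The list mean was 7.86 on Ebf2-positive replicate 2, 6.34 and 6.72 on Ebf2-positive replicates 1 and 3, and 7.02, 8.01 and 7.43 on the Ebf2-negative arrays.

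**Figure D4:**
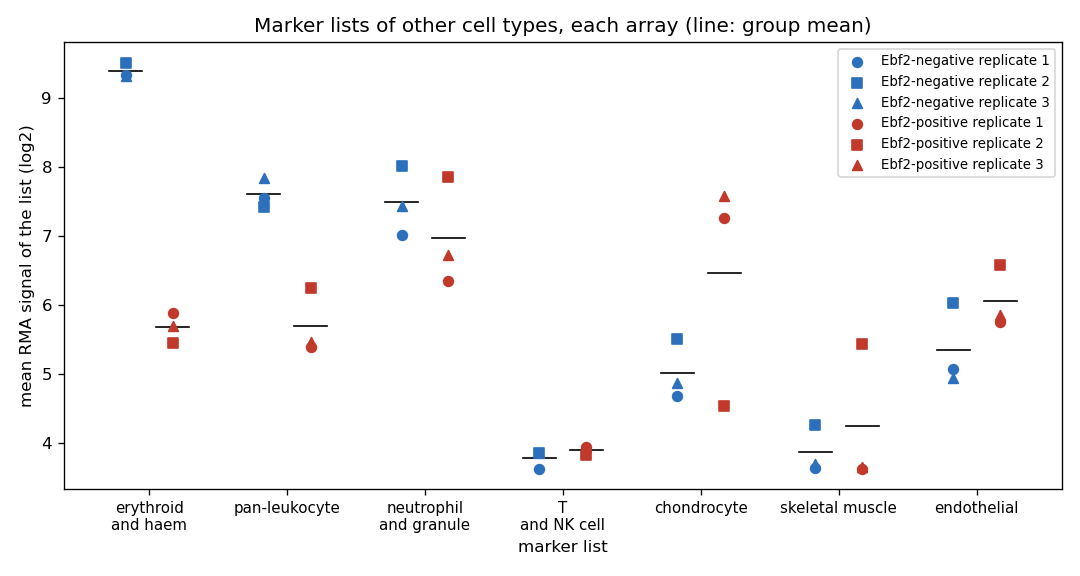
Mean RMA signal (log2, vertical axis) over the measured members of 7 marker lists on each array (red, Ebf2-positive; blue, Ebf2-negative; circle, square and triangle for replicates 1, 2 and 3), with a line at each group mean. Erythroid means lie between 5.45 and 5.89 in Ebf2-positive and between 9.31 and 9.51 in Ebf2-negative cells, and Ebf2-positive replicate 2 stands at 4.55 for chondrocyte and 5.44 for skeletal muscle genes.

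A few endothelial genes were higher in Ebf2-positive cells. Of 22 members, 4 were higher and 1 lower, also adjusted over the list alone, with a median of 0.61, or -1.88 with poly-A centring (camera adjusted p = 0.0457, but 0.247 without Ebf2-positive replicate 2, 0.123 without Ebf2-negative replicate 1 and 0.168 without Ebf2-negative replicate 3; adjusted p = 0.682 with an estimated correlation). Ramp2, a receptor-modifying protein of the adrenomedullin pathway (3.31), Tek, the angiopoietin receptor (2.51), and Esam, a cell adhesion molecule (2.48), were higher, while Pecam1 was not called. Flt1, a receptor of vascular endothelial growth factor named after its value was seen (1.54), kept its call only without Ebf2-negative replicate 2 (adjusted p up to 0.11, without Ebf2-negative replicate 3), and the lower member Lyve1, a hyaluronan receptor (-1.78), only without Ebf2-negative replicate 3 (up to 0.143, without Ebf2-negative replicate 1). Of 15 Schwann cell and neural genes, 2 were higher and 1 lower, also adjusted over the list alone (median 0.13, camera adjusted p = 0.494). Pmp22, a myelin protein that fibroblasts also make, was higher (4.72), as was Ngfr, a neurotrophin receptor (1.66), lost without Ebf2-positive replicate 1 or any Ebf2-negative array (adjusted p up to 0.077, without replicate 3 of the latter). Mbp, myelin basic protein, was lower (-2.89), but not without any of the Ebf2-negative arrays (0.0788, 0.0673 and 0.0786 without replicates 1, 2 and 3), and 2 members were lower without Ebf2-positive replicate 1. Of 18 skeletal muscle genes, 1 was higher, Tnnt3, a fast-muscle troponin (1.44), and 0 adjusted over the list alone (median 0.32, camera adjusted p = 0.472). Tnnt3 was lost without Ebf2-positive replicate 3 or any Ebf2-negative array (adjusted p up to 0.141, without Ebf2-negative replicate 1), and 2 members were higher without Ebf2-positive replicate 2.

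Cell-division genes were lower and several cell-cycle inhibitors higher in Ebf2-positive cells. Of 29 proliferation genes, 0 were higher and 26 lower, also adjusted over the list alone, with a median of -3.53 (camera adjusted p = 2.48e-16; adjusted p = 0.156 with an estimated correlation). Mki67, the proliferation antigen, was at 5.79 ± 1.54 against 10.92 ± 0.26 (-5.13), Bub1, a spindle checkpoint kinase, differed by -5.01, Kif20a, a mitotic kinesin, by -4.65 and Nusap1, a spindle protein, by -4.55. Erythroid genes were lower on the same arrays by a similar amount (median -3.85), as was Myb, a transcription factor of blood progenitors named after its value was seen (-4.24). Of 16 cell-cycle inhibitor and quiescence genes, 5 were higher and 1 lower (8 and 1 adjusted over the list alone), with a median of 0.66, or -1.83 with poly-A centring (camera adjusted p = 0.0343, but 0.0631 without Ebf2-positive replicate 2, 0.0913 without Ebf2-positive replicate 3 and 0.054 without Ebf2-negative replicate 3; adjusted p = 0.209 with an estimated correlation). They were Gas1, a growth-arrest protein (3.99), Txnip, an inhibitor of thioredoxin (2.11), Foxo1, a transcription factor of quiescence (1.92), Cdkn1a, a cyclin-dependent kinase inhibitor (1.82), and Cdkn2b, another such inhibitor (1.60). Cdkn2b and the lower member, the inhibitor Cdkn2c (-1.51), were named after their values were seen. Cdkn2b lost its call without Ebf2-negative replicate 1 (adjusted p = 0.0652) or 2 (0.0627), and Cdkn2c without Ebf2-positive replicate 1 (0.0532) or 3 (0.0517).

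Ribosomal protein and oxidative phosphorylation genes were lower by a small margin, and immediate early genes were higher. Of 20 ribosomal protein genes, 0 were higher and 12 lower (0 and 17 adjusted over the list alone), with a median of -0.95 (camera adjusted p = 1.14e-06; adjusted p = 0.252 with an estimated correlation). The erythroid and proliferation lists were lower on the same arrays, with medians of -3.85 and -3.53. Rpl4, of the large subunit, differed by -1.24, and the count of lower genes was 3 without Ebf2-negative replicate 2 and 2 without replicate 3. Of 23 oxidative phosphorylation genes, 0 were higher and 11 lower (0 and 18 adjusted over the list alone), with a median of -1.03 (camera adjusted p = 3.68e-07; adjusted p = 0.209 with an estimated correlation). Atp5b, a subunit of ATP synthase (-1.51), and Uqcrc2, of respiratory complex III (-1.50), were lower, and the count was 7, 6 and 4 without Ebf2-positive replicate 3 and Ebf2-negative replicates 2 and 3. Of 22 glycolysis and hypoxia genes, 9 were higher and 3 lower (9 and 7 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.345), and 5 were higher without Ebf2-negative replicate 3. Slc2a1, a glucose transporter (5.43), and Ndrg1, a hypoxia-responsive gene (2.16), were higher. Slc2a3, another glucose transporter (-2.90), was lower, as were Ldha, lactate dehydrogenase (-1.13), and Tpi1, triosephosphate isomerase (-0.89), both named after their values were seen, the latter called only without Ebf2-positive replicate 3 (adjusted p up to 0.128, without Ebf2-negative replicate 3). Of 27 immediate early and heat shock genes, 18 were higher and 2 lower (21 and 3 adjusted over the list alone), with a median of 1.83, or -0.67 with poly-A centring (camera adjusted p = 3.28e-07; adjusted p = 0.156 with an estimated correlation). Klf4 (4.35) and Klf2 (3.34), zinc finger factors, and Atf3 (3.38) and Fosl2 (3.10), leucine zipper factors, had the largest differences. The lower members, named after their values were seen, were Myc, a growth regulator (-1.78), and Hsph1, a heat shock protein (-1.73), the latter not without Ebf2-negative replicate 1 (adjusted p = 0.0679) or 3 (0.0674).

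Chemokine and interferon-response genes moved in both directions. Of 32 chemokine and cytokine genes, 5 were higher and 3 lower, also adjusted over the list alone (median 0.25, camera adjusted p = 0.179). Ccl11, the eosinophil chemokine eotaxin, was at 8.76 ± 0.84 against 2.94 ± 0.26 (5.82), Il33, an alarmin of stromal cells, was higher by 5.46 and Cxcl13, a B-cell chemokine, by 5.16. Cxcl1, a neutrophil chemokine (4.37), and Csf1, the macrophage growth factor (1.23), were also higher, and Csf1 kept its call only without Ebf2-negative replicate 2 (adjusted p up to 0.112, without Ebf2-negative replicate 3). Ccl3, an inflammatory chemokine, was lower (-4.90), as were the monocyte chemokines Ccl6 (-3.15) and Ccl9 (-3.29). Ccl6 lost its call without Ebf2-positive replicate 1 (adjusted p = 0.054) or Ebf2-negative replicates 1 (0.0768) and 3 (0.0786), and Ccl9 without Ebf2-negative replicates 1 (0.0503) and 3 (0.0571). Cxcl1, Csf1, Ccl6 and Ccl9 were named after their values were seen. In this list 8 members were higher without Ebf2-negative replicate 2, and 5, 1 and 1 were lower without Ebf2-positive replicate 2 and Ebf2-negative replicates 1 and 3. Of 24 interferon-response genes, 2 were higher and 1 lower, also adjusted over the list alone (median -0.05, camera adjusted p = 0.755). Rsad2, the antiviral protein viperin, was lower (-4.52, 7.51 ± 0.48 against 12.03 ± 0.36), and Gbp2, a guanylate-binding protein (2.64), and Ifi27, an interferon-induced protein (1.64), were higher, while 2 members were lower without Ebf2-positive replicate 2 or Ebf2-negative replicate 1. Of 13 complement and acute phase genes, 3 were higher and 0 lower, also adjusted over the list alone, with a median of 1.07, or -1.43 with poly-A centring (camera adjusted p = 0.0362, but 0.143 without Ebf2-positive replicate 2, 0.0815 without Ebf2-negative replicate 1 and 0.0562 without Ebf2-negative replicate 3; adjusted p = 0.538 with an estimated correlation). They were the proteases C1s1 (3.61) and C1ra (3.26) of the classical pathway and C2 (2.45), which was lost without Ebf2-positive replicates 1 and 3 or Ebf2-negative replicates 1 and 3 (adjusted p up to 0.0957, without Ebf2-negative replicate 3), and 6 members were higher without Ebf2-negative replicate 2.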

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

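The tests of the leukocyte and erythroid patterns that were chosen only after the result was seen are those of erythroid cells, of the poly-A against the hybridization controls, of the replicate spread, of neutrophils and of the other mature leukocytes. The splits of the arrays and the comparison with random lists were set beforehand. The test of early progenitors was set after Tal1 and Bcl11a had been seen, but before the values of its other members were. Mpo and Erg are exceptions, since they belonged to lists already tested.

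The added control transcripts, which the comparison of genes in the report did not use, were brighter on the Ebf2-positive arrays. The poly-A controls, mixed into the RNA before amplification, differed by 2.49 on the log2 scale (12.31 ± 0.21 against 9.82 ± 0.99, n = 3, 5.63-fold) and the hybridization controls, added to the labelled product, by 1.54 (12.55 ± 0.59 against 11.00 ± 0.43, 2.92-fold), each with a two-sided exact permutation p of 0.1, the smallest possible. A candidate explanation, left open, is that less sample RNA entered amplification from the Ebf2-positive cells. The replicate spread does not decide it: the median SD ratio was 1.38 over 5 bins of signal level (1.74, 1.65, 1.38, 1.01 and 0.80 from dim to bright), but this is a spread between separately sorted samples, and Ebf2-positive replicate 2 stood apart from the other 2 of its group. Whether less labelled product was hybridized in addition cannot be told apart, since the excess of the poly-A over the hybridization difference was 0.95 (pooled SD 0.74, exact permutation p = 0.2). A biological difference in RNA content per cell and unequal cell numbers remain open, because the array of each cell number is not given in the sources used here.

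Erythroid genes were lower in Ebf2-positive cells although TER119-positive cells were gated out of both groups. The list median of -3.85 lay below the lowest of 10000 random lists matched on level in the Ebf2-negative arrays (-2.17). The erythroid genes thus fell further than other genes of similar level. This does not decide on a weaker signal for all genes on the Ebf2-positive arrays, since quantile normalization removes such a shift beforehand. A candidate explanation, as a hypothesis, is that the Ebf2-negative gate held erythroid-lineage cells with little TER119. That 95.7% of the erythroid genes (22 of 23) were lower by at least 1 on the log2 scale restates the pattern. Erythroid transcripts were present in the Ebf2-negative samples, with Rhag at 9.50 ± 0.21 and Gata1 at 10.49 ± 0.16. These values do not decide which cells the transcripts came from or how much TER119 such cells held, so the hypothesis stays open. In Ebf2-negative cells Car1, Car2, Tfrc and Klf1 were bright (13.0, 12.9, 11.6 and 11.6), while the alpha-globin probe set was dim in both groups and says nothing.

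Pan-leukocyte genes were lower in Ebf2-positive cells although CD45 was gated out. T cells as the main source were argued against by the median of their list, 0.20 (bootstrap interval 0.13 to 0.27). It lay above the bound of -0.95 for a main source, which was set after the result was seen. The medians of macrophage (-0.0067, interval -0.28 to 0.10) and B-cell genes (0.00, interval -0.64 to 0.39) also lay above it. Those lists hold higher members such as Ctsk (3.06) and Ebf1 (4.11) beside lower ones such as Mrc1 (-2.62) and Ighm (-2.17). Their medians therefore do not exclude macrophages or B cells. Neutrophils stay open, with a median of -0.66 and an interval of -1.60 to 0.72 that holds the bound; without Ebf2-positive replicate 2 the neutrophil list was called lower (median -0.87, interval -1.76 to 0.21; camera adjusted p = 0.0112), as it was without both arrays numbered 2 (0.0429). Early haematopoietic progenitors among the Ebf2-negative cells stay open as a hypothesis: of 18 measured progenitor genes other than Tal1 and Bcl11a, which were lower and had been seen before the test, 10, or 55.6%, were lower and 1 (Mpo) higher (camera p = 0.000937; with an estimated correlation p = 0.0232, adjusted p = 0.062), and 10 of 16 without Mpo and Erg, which lists fixed earlier also hold. Most of these genes, such as Myb (-4.24), Kit (-3.92) and Lyl1 (-2.86), are also active in erythroid progenitors, whereas Hlf (1.96), Mecom (1.43), Meis1 (0.82), Flt3 (0.25) and Erg (0.07) were not called (adjusted p = 0.103, 0.259, 0.169, 0.402 and 0.941), so both accounts of the marrow cells remain open.

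The count of 4430 genes was set against the other ways of dividing the 6 arrays into 3 and 3. The 10 splits, of which 1 gave as many genes, are too few for a share under 0.05. The highest count of the others was 0. Each of those splits mixes the groups, which puts the difference between groups into the spread, so that count does not bear on chance.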

How the results depend on the processing

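Poly-A centring and the fit without both arrays numbered 2 were chosen after seeing the data. The gene count stayed within 1.5 times of 4430 under the scaling, filter, probe set and variance alternatives (4070 to 4636 genes, with 4123 shared under the trend and robust model). It fell to 1433 (775 higher, 658 lower) with a minimum log2 difference of 1, and the probe set count to 1804 (919 and 885), as that stricter question implies. Without both arrays numbered 2, lower genes numbered 1642, and probe sets 4147, of which 2156 were lower. With poly-A centring 15890 genes were called, 227 higher and 15663 lower, and 2823 were shared with the 4430, since every value then shifts. Leaving out 1 array gave 2690 to 4348 genes (1294 to 1877 higher, 1396 to 2471 lower), 3526 to 6697 probe sets (1599 to 2827 higher, 1927 to 3870 lower), 17 to 23 called lists (10 to 17 higher, 6 to 7 lower), Ebf2 differences of 4.39 to 4.85, Pecam1 differences of 0.27 to 0.96 and Ptprc differences of -3.20 to -1.61. Ebf2 stayed called under each alternative run for it and Pecam1 uncalled, except that the median filter removed Pecam1 and gave no value. Ptprc, uncalled at -2.65, passed with the filter at the median (-2.65, adjusted p = 0.0268) and at the 25th percentile (-2.65, adjusted p = 0.0453) and with array weights (-2.75, adjusted p = 0.0384). The filters test fewer genes, and the cause was not tested for the weights. With an estimated correlation 0 lists were called (0 higher, 0 lower), and fry called 19 (13 higher, 6 lower), of which 18 were shared with camera. The calls lost with fry were those of niche factor, adipocyte, chondrocyte, endothelial and complement genes (fry adjusted p = 0.0616, 0.0855, 0.159, 0.229 and 0.0617). Laptm5, a lysosomal protein of blood cells, turned from -2.64 to 0.19 (adjusted p = 0.645) without probe sets that can cross-hybridise, which picks another probe set for the gene. Over 132 named genes, 2358 values under an alternative gave 2199 on the same side of the threshold, 153 weaker, 5 stronger and 1 reversed.

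The list calls of adipocyte genes (adjusted p = 0.0558) were lost with array weights, those of osteoblast, endothelial and complement genes with array weights (0.0595, 0.0624 and 0.0756) and 75th percentile centring (0.0667, 0.0595 and 0.0524), those of osteoblast and endothelial genes with the trend and robust model (0.0567 and 0.0571), that of complement genes without probe sets that can cross-hybridise (0.128), and those of HOX (0.0688) and megakaryocyte genes (0.0564) with the median filter. Of the 132 genes named by the set rule, 23 lost their call without 1 array: Adm, C2, Cdca5, Cebpd, Chil3, Cycs, Hoxa11, Hoxc8, Hoxc10, Klf15, Laptm5, Lyve1, Mbp, Mmp9, Mpo, Ndufb5, Ngfr, Prtn3, Rpl14, Rps6, Rps19, Sparc and Tnnt3. The labels number the replicates 1 to 3 in both groups but do not say what a number shares. For that reason, fixed beforehand, the numbers were not taken to pair the samples. Deviations of same-numbered arrays correlated by 0.058, 0.106 and 0.029, and 5 of 6 arrays correlated best with their own number. This is a hint of pairing from the data and not the design. With the replicate block 4219 genes were called, 3856 of them shared, with 5999 probe sets and 22 lists, and the osteoblast list lost its call (adjusted p = 0.075). Signal near background limits the dim genes.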

Other observations

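The tests in this part were set after the lists of the largest differences had been read but before the values of the added genes were seen, except Pparg, which belonged to a list already tested; the genes noted as already seen were left out of each test, and the genes named here were chosen after their values were seen.

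Genes of tendon, ligament and joint lining were higher in Ebf2-positive cells. Of 14 such genes outside those already seen, 9 were higher and 0 lower, with a median of 2.47 that falls just below 0 with poly-A centring (limma camera p = 1.27e-05; with an estimated correlation p = 0.00973, adjusted p = 0.0584). The higher members fit the hypothesis that synovial or tendon cells may be part of the Ebf2-positive population, which stays open. Thbs4, a thrombospondin of tendon, differed by 5.26, Kera, the proteoglycan keratocan, by 4.33, Htra1, a secreted protease, by 3.69 and Prelp, a connective tissue proteoglycan, by 3.29. The remaining members Mkx (1.27), Cthrc1 (1.38), Tnc (-0.29), Crtac1 (-0.05) and Col12a1 were not called (adjusted p = 0.118, 0.223, 0.589, 0.887 and 0.0687). Of the genes left out as already seen, Scx was not called (0.33, adjusted p = 0.265), and the others, such as Tnmd (3.51), were higher. Other fibroblasts express several of the higher genes, so the test does not separate the sources.

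Some axon guidance factors were also higher. Sema3c, which stood high, prompted this list and was left out. Of 27 other semaphorin, ephrin, netrin and neurotrophin genes, 13 were higher and 1 lower, with a median of 1.33 that turns negative with poly-A centring (camera p = 2.45e-05, and with an estimated correlation p = 0.0799, adjusted p = 0.0799). The count of higher members was 9 without Ebf2-negative replicate 1 or replicate 3. The hypothesis that the class is higher in these cells stays open. Ntn1 (4.59) and Ntn4 (4.45), both netrins, Sema3e, a semaphorin (4.47), and Slit3, a ligand of Robo receptors (3.38), were the largest. The lower member, Epha7 (-0.67), lost its call without any 1 of the arrays (adjusted p up to 0.137, without Ebf2-negative replicate 1).

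Imprinted genes were tested as a class because Meg3 and Ndn stood high. Of 16 others, 6 were higher and 1 lower, with a median of 1.03 that turns negative with poly-A centring (camera p = 0.00234; with an estimated correlation p = 0.031, adjusted p = 0.062). Sgce, a sarcoglycan (3.27), Peg3, a zinc finger protein (2.85), and Igf2, a fetal growth factor (2.01), were higher, and Peg3 lost its call without Ebf2-negative replicate 3 (adjusted p = 0.0516). The count of higher members was 3 without Ebf2-negative replicate 2 and 2 without Ebf2-negative replicate 3. Phlda2, a growth-restraining gene, was lower (-2.05), but not on leaving out any array except Ebf2-positive replicate 3 (adjusted p up to 0.14, without Ebf2-negative replicate 3).

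Ebf2 marks precursors of brown fat in other tissues, so a brown or beige adipocyte list was tested. Of 18 genes, 4 were higher and 0 lower, with a median of 0.52 that turns negative with poly-A centring (camera p = 0.00198; with an estimated correlation p = 0.0723, adjusted p = 0.0799). Pparg, which the adipocyte list also holds, was kept in this test, and without it, a choice made after seeing the data, camera p was 0.00328 (0.0675 with an estimated correlation). The count of higher members was 2 without any 1 of the Ebf2-positive arrays and 1 without any 1 of the Ebf2-negative arrays. Only Tmem26 (2.82) among them kept its call on leaving out each array, while Dio2, Tnfrsf9 and Epsti1 lost it (adjusted p up to 0.107, 0.119 and 0.151, without Ebf2-negative replicate 3, 1 and 3). The thermogenic genes Ucp1 (0.09), Cidea (0.53) and Prdm16 (0.79) were not called.

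Some mast cell and basophil genes were lower in Ebf2-positive cells beyond Mcpt8 and Ms4a2, which had been seen. Of 11 others, 4 were lower and 0 higher, with a median of -0.45 (camera p = 0.00763; with an estimated correlation p = 0.0643, adjusted p = 0.0799), although the CD45 gate should remove such cells. They were Fcer1a, a chain of the IgE receptor (-4.64), Kit, the stem cell factor receptor (-3.92), Cpa3, a granule protease (-2.56), and Gata2, a transcription factor (-2.48), where Kit and Gata2 also belong to the progenitor list. The other 7, Hdc (-1.79), Tpsb2 (-0.45), Cd200r3 (-0.43), Il4 (-0.16), Tpsab1 (-0.04), Cma1 (0.19) and Mcpt4 (0.44), were not called. Cpa3 lost its call without Ebf2-negative replicate 3 (adjusted p = 0.0507) and Gata2 without Ebf2-negative replicate 1 (0.0741) or 3 (0.0814), so 2 members were lower without Ebf2-negative replicate 3.

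Ebf2-positive replicate 2 differed from the others of its group in several cell types at once, and no explanation was tested. Col2a1, the type II collagen of cartilage, was at 11.37 and 11.57 on Ebf2-positive replicates 1 and 3 and at 5.95 on replicate 2. Acta1, skeletal muscle actin, was at 5.10 and 5.11 against 9.51. Ltf, lactoferrin of neutrophil granules, was at 6.17 and 7.54 against 9.97, and Lyz2, lysozyme of myeloid cells, at 5.97 and 6.16 against 9.41. The Ebf2-negative arrays had Ltf at 9.95, 10.60 and 9.86 and Lyz2 at 8.93, 9.53 and 8.96. Skeletal muscle list means were 5.44 on Ebf2-positive replicate 2 and 4.26 on Ebf2-negative replicate 2, with 3.63 to 3.70 on the other arrays. Both arrays numbered 2 also had the highest endothelial mean of their group, at 6.58 and 6.02.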
